A study of Mus musculus with 12 samples.

How the data were processed

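RNA was measured in 12 libraries of mouse PYMT cells in 4 groups of 3 biological replicates each. The name is that of the mammary tumour model driven by the polyoma middle T antigen. Cells grown in matrigel received TGFB2, BMP4, both, or neither (NT). Each ligand was given at 5 ng/mL for 3 days. Cells were harvested 2 days after a change of medium. The labels call the replicates biological and do not say what separated them, so p-values measure the spread between these cultures.

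Libraries were made from RNA enriched with oligo(dT) beads by a kit of the NEBNext Ultra II series, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.7.5b and Salmon 1.2.1 were used with the GRCm38.p6 build. The role of each tool and its settings are not given in the sources used here. The authors deposited a table of estimated counts per gene from Salmon, per the file headers. Of these values 82.9% were whole numbers. They were rounded here, which changed the total by 0.000361%. A deposited normalized signal table held the counts divided by 1 size factor per library. Over 8580 genes with a mean count above 500, the ratio within a library ranged by at most 0.265%, with factors from 0.844 to 1.24. A deposited TPM table, scaled for length and depth by the authors, summed to the same total in each library. Other deposited fields, per the file headers, gave the same sequencing batch, an unstranded library type and a passed quality check for all 12 libraries. With unstranded reads, a gene and a partner that shares its exons are not told apart by strand. Where the partner had more than 10% of the gene's mean CPM, this is stated at the gene. Bhlhe41, Cdkn1a, E2f8, Fn1, H2-T22, Has2, Klk14, Lama3, Lox, Ltbp2, Prss23, Tnc and Wnt7b share exons with a tested partner of at most 5.62% of their mean CPM. That highest share was of Klk14, whose partner 2310002F09Rik averaged 2.64 CPM, above the 1.66 CPM of Klk14 with TGFB2.

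Totals ran from 28543100 to 42167800 counts. Of 54347 genes, 15319 passed the edgeR function filterByExpr with its minimum count of 10. These held 99.9% of all counts. TMM factors lay between 0.971 and 1.03, and the common biological coefficient of variation was 0.299. Comparisons used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with all 12 libraries in a single model by group, since the groups come from a single experiment. There were 7 comparisons: each treatment against NT, the treatments against each other, and the interaction of the ligands on the log2 scale. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and the number with an absolute log2 fold change of at least 1 is given beside it. Values after ± are SE for log2 fold changes and SD over 3 libraries for CPM, the counts of a gene scaled to the library total. All adjusted p-values of genes are from edgeR unless another tool is named. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 17.9.

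The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. There were 31 lists with 787 genes: ligand responses and pathway parts, dormancy, cell cycle and quiescence, epithelial, mesenchymal, matrix, luminal, basal and cytoskeletal genes, interferon, antigen presentation and cytokines, lipid and energy metabolism, stress, p53, retinoic acid, Wnt, Notch and immediate early genes, markers of leukocytes, endothelium, fibroblasts, adipocytes and erythroid cells, and mitochondrial and ribosomal protein transcripts. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 31 lists within a comparison. Camera with a correlation estimated per list stands beside it, and fry gave counts of lists as an alternative. With the estimated correlation 1 list passed in a single comparison, the BMP list in BMP4-TGFB2 against TGFB2, and no list passed in the other 6. Not every list called by camera is described in each comparison.

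Named genes were, for each treatment against NT, the 8 largest rises and 8 largest falls among genes that passed, with a mean log2 CPM of at least 2 and every library of one group above every library of the other. Predicted genes, clone names and unnamed identifiers were skipped. Other comparisons took 5 per direction, the interaction without the condition on separated libraries. From each list up to 4 members with the smallest p were named, and always a fixed set that included Nr2f1, Cdkn1b, Cdkn1a, Sox9, Mki67, Id1, Smad7, Cdh1, Vim, Fn1, Tgfb2 and Bmp4. Genes chosen otherwise are marked where they stand. Positions are from GENCODE M21 on GRCm38, in which 317 of the 328 named identifiers were found with the same version.

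Replicate numbers in the labels could pair libraries across groups. The deviations of same-numbered libraries from their group means correlated across genes above 0.1 for each of the 3 pairs in BMP4 against NT (0.16 to 0.44), BMP4 against TGFB2 (0.15 to 0.35), BMP4-TGFB2 against BMP4 (0.15 to 0.35) and BMP4-TGFB2 against TGFB2 (0.23 to 0.50). These were treated as paired by that check alone, and the value with the replicate number as a block stands beside their results where it changed a call. The other comparisons did not meet it, which does not show that their libraries were unpaired. Genes that did not pass there were judged without the block, so some of them may pass with it. With the block 5764 genes passed against 3427 for TGFB2 against NT, and 6328 against 4008 for BMP4-TGFB2 against NT.

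Alternatives were RLE size factors, no filter beyond 1 count, DESeq2 1.42.0, limma voom, limma on log2(TPM + 1), the replicate block, only the groups compared in the model, and each library left out in turn. A further alternative, all replicate 1 libraries left out, was chosen after seeing the data, because they stood apart on the second principal component. It leaves 2 libraries per group and takes out those with the lowest cell cycle list means with TGFB2 and with both ligands. The model was tested on simulated data, with 200 genes changed by known amounts. For TGFB2 against NT (14887 genes) it recovered 37.3%, 61.2% and 83.3% of genes changed by 1, 2 and 3 log2 units, with 3 false calls among 124. For BMP4-TGFB2 against TGFB2 (14885 genes) the shares were 43.3%, 53.7% and 72.7%, with 3 false among 116. For the interaction (14904 genes) they were 4.48%, 56.7% and 59.1%, with 4 false among 84.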

Results

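Gene expression was measured by poly(A) RNA sequencing in 12 libraries of mouse PYMT cells, named for a mammary tumour model and grown in matrigel. TGFB2 and BMP4 are secreted ligands of the transforming growth factor beta family. TGFB2 acts through SMAD2 and SMAD3, BMP4 through SMAD1 and SMAD5. The study asked which gene programs each ligand, alone or with the other, sets in motion in relation to dormancy, a lasting arrest of tumour cells. Each group, NT, TGFB2, BMP4 and BMP4-TGFB2, had 3 libraries, with total counts of 28543100 to 42167800. Transcripts encoded by mitochondria took 1.04% to 2.23% of the counts.

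The first principal component of log2 CPM, with 43.3% of the variance, placed NT and BMP4 libraries on one side and both groups with TGFB2 on the other. The second, with 14.4%, ordered the replicate numbers alike in every group. Replicate 1 libraries scored 37.5 to 49.7, replicate 2 libraries -11.8 to -5.61 and replicate 3 libraries -40.1 to -27.6. Pearson correlations across genes ran from 0.96 to 0.982 within groups and from 0.907 to 0.98 between them.

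**Figure D1:**
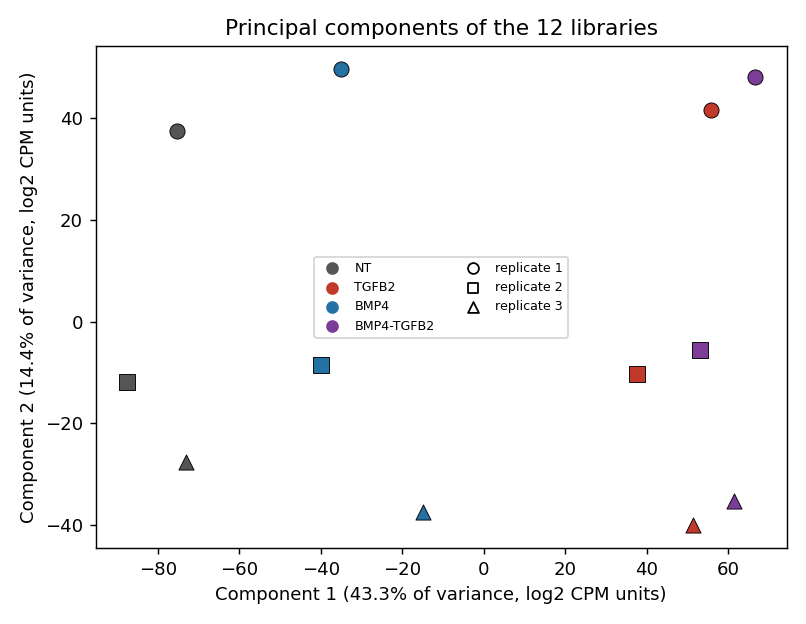
Scores of the 12 libraries on the first 2 principal components of log2 CPM, by group (colour) and replicate number (shape). The groups with TGFB2 lie to the right, and the replicate 1 library of each group lies highest on component 2.

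With TGFB2 alone Itgb3 and Adgra1 were among the largest rises, and Ltf and 2 casein genes among the largest falls. Itgb3, an integrin subunit (ENSMUSG00000020689.4, chromosome 11, 104608000 to 104670476), went from 0.585 ± 0.35 CPM to 39.2 ± 15.4 CPM, a log2 fold change of 6.07 ± 0.63 (SE; adjusted p = 0.00010; n = 3 per group). Adgra1, an adhesion receptor, rose by 7.56 ± 0.77, the receptor phosphatase Ptpru by 5.76 ± 0.37 and the hyaluronan synthase Has2 by 5.72 ± 1.16 log2 units. Lactotransferrin, Ltf (ENSMUSG00000032496.7, chromosome 9, 111019271 to 111042767), an iron-binding milk protein, dropped from 10250 ± 3152 CPM to 90.8 ± 13 CPM (-6.82 ± 0.39; adjusted p = 3.04e-06). The casein genes Csn1s1 (-7.45) and Csn3 (-7.38) fell too, as did Pip (-7.74), the immunoglobulin transporter Pigr (-7.76), the chemokine Ccl28 (-6.39) and the kallikreins Klk14 (-6.14) and Klk10 (-5.92). The protease inhibitor Ctla2a rose by 6.45 ± 0.47, but shares exons with a predicted gene. Among the 8 largest rises, Mmp9 no longer passed with no filter on low counts or in limma voom (adjusted p 0.0545 to 0.0715), at a log2 fold change of 7.35. Tnc no longer passed without NT replicate 1, 2 or 3 or TGFB2 replicate 3, with no filter on low counts, in limma voom or with every replicate 1 library left out (adjusted p 0.0528 to 0.126), at 5.95.

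Targets of SMAD2 and SMAD3 rose with TGFB2. Of 26 measured members of the TGFb SMAD2/3 response list, 18 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.32e-08, and adjusted p = 0.235 with an estimated correlation). Over all genes, 17 rose and 0 fell, with Pmepa1 (2.24), Smad7 (1.63), Skil (1.47) and Bhlhe40 (1.92) as examples, the first 3 of them feedback inhibitors of the pathway. The BMP SMAD1/5 response list, with 21 members measured, had 5 that rose and 3 that fell adjusted over the list alone (camera adjusted p = 0.397). Over all genes 4 rose and 2 fell: Smad6 rose (1.48), while Id2 (-1.21) and Atoh8 (-2.10) fell. In the TGFb and BMP ligands, receptors and SMADs list, 11 of 32 measured members rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.468 with an estimated correlation). A total of 10 rose and 3 fell over all genes. The procollagen protease gene Bmp1 (2.41), the activin antagonist Fstl3 (2.87) and Bmp2 (3.62) rose, and Tgfb2 itself fell (-1.79). The mesenchymal and EMT genes list, with 24 members measured, had 12 that rose and 0 that fell adjusted over the list alone (camera adjusted p = 4.89e-06, and adjusted p = 0.44 with an estimated correlation). Over all genes 12 rose and 0 fell, among them Snai1 (1.77), Fn1 (3.40) and Ncam1 (2.85), a transcription factor, fibronectin and an adhesion molecule. Of 35 measured members of the collagens and extracellular matrix list, 15 rose and 0 fell adjusted over the list alone (camera adjusted p = 1.72e-06, and adjusted p = 0.44 with an estimated correlation). Over all genes, 14 rose and 0 fell. Examples were P4ha1 (1.78), Col7a1 (4.61) and Lama3 (3.40). Of the fibroblast markers, 5 of 13 rose, including Pdgfra (2.37), Col1a1 (2.14) and Lox (4.26) (camera adjusted p = 0.0115, and adjusted p = 0.517 with an estimated correlation). Col1a1 is in the matrix list as well. In the actin cytoskeleton and YAP targets list, 11 of 24 measured members rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000671, and adjusted p = 0.517 with an estimated correlation). A total of 10 rose and 2 fell over all genes, with Pdlim7 (2.51) and Fhl2 (3.58) up and F3 (-1.87) down.

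Of 20 measured members of the luminal and milk genes list, 2 rose and 11 fell adjusted over the list alone (camera adjusted p = 3.23e-06, and adjusted p = 0.235 with an estimated correlation). Over all genes, 2 rose and 9 fell. Beside the caseins and Ltf this included Elf5 (-3.91 ± 0.31), the transcription factor of secretory differentiation. The epithelial junction and identity genes list, with 30 members measured, had 3 that rose and 11 that fell adjusted over the list alone (camera adjusted p = 0.0277, and adjusted p = 0.52 with an estimated correlation). Over all genes 1 rose and 8 fell. The tight junction gene Cldn1 (-3.58) and the factor Grhl1 (-2.79) fell and Cldn4 (2.73) rose, while Cdh1, E-cadherin, stood at -0.29 ± 0.10 (adjusted p = 0.0519). In the basal and myoepithelial genes list, 8 of 17 measured members rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0449, and adjusted p = 0.517 with an estimated correlation). A total of 3 rose and 2 fell over all genes (6 and 2 without the replicate 1 libraries), with Procr (3.09) up and Itga6 (-1.50) down.

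Interferon-stimulated genes fell almost throughout. Of 34 measured members of the interferon response list, 0 rose and 33 fell adjusted over the list alone (camera adjusted p = 6.37e-23, and adjusted p = 0.34 with an estimated correlation). Over all genes, 32 fell and 0 rose, with Oas1a (-2.91), Oas3 (-3.17), Cmpk2 (-3.86) and Gbp3 (-3.91) as examples, which encode antiviral enzymes and a GTPase. Without the replicate 1 libraries 31 fell and 1 rose. The library means of this list ran from -0.58 to 0.82 log2 units in NT and from -3.24 to -2.80 with TGFB2, relative to the NT mean. The MHC class I antigen presentation list, with 16 members measured, had 0 that rose and 13 that fell adjusted over the list alone (camera adjusted p = 1.72e-06, and adjusted p = 0.42 with an estimated correlation). A total of 12 fell and 0 rose over all genes, such as H2-K1 (-1.06), H2-T22 (-1.31) and Psmb8 (-2.29). In the NF-kB, cytokines and acute-phase genes list, 4 of 34 measured members rose and 14 fell adjusted over the list alone (camera adjusted p = 0.0347, and adjusted p = 0.517 with an estimated correlation). A total of 4 rose and 12 fell over all genes, with the chemokines Cxcl3 (-4.01) and Ccl20 (-3.87) and Tnfaip2 (-1.55) and Csf3 (-1.36) down. Without the replicate 1 libraries the camera adjusted p of this list was 0.323. Of 7 measured leukocyte markers, 2 rose (camera adjusted p = 0.0948): Csf1r (3.65), which shares exons with the more abundant Hmgxb3, and Laptm5 (0.085 ± 0.0322 CPM in NT and 0.427 ± 0.33 CPM with TGFB2). Laptm5 no longer passed without NT replicate 1, 2 or 3 or TGFB2 replicate 2 or 3, with no filter on low counts, in limma voom, in limma on TPM or with every replicate 1 library left out (adjusted p 0.0588 to 0.232).

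Proliferation genes differed between replicates. Of 42 measured members of the cell cycle and DNA replication list, 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00049, and adjusted p = 0.67 with an estimated correlation). Over all genes, 0 fell and 0 rose, so the list ranked low as a set while no single member passed. E2f8 stood at -1.50 ± 0.63 (adjusted p = 0.116), Uhrf1 at -1.23 ± 0.58 (0.162) and Mki67, a marker of cycling cells, at -1.48 ± 0.85 (0.243). The list mean relative to NT was -2.35 log2 units in TGFB2 replicate 1, against -0.27 and -0.35 in replicates 2 and 3, and -0.41 in NT replicate 1. Without the replicate 1 libraries 26 of 42 members fell and 0 rose, with a median of -0.53. The camera adjusted p was then 1.75e-09, at the preset correlation only. The inhibitor of cyclin-dependent kinases Cdkn1a rose (1.44 ± 0.31; adjusted p = 0.00716), and Cdkn1b did not pass (-0.45 ± 0.20; 0.138). In the CDK inhibitors and quiescence list, 4 of 24 measured members rose and 4 fell adjusted over the list alone (camera adjusted p = 0.859). A total of 3 rose and 3 fell over all genes (6 and 2 without the replicate 1 libraries), with Hes1 (0.87) up and Cdkn2c (-1.39) down. The p53 targets list, with 24 members measured, had 10 that rose and 0 that fell adjusted over the list alone (camera adjusted p = 0.000261, and adjusted p = 0.468 with an estimated correlation). Over all genes 8 rose and 0 fell (13 and 0 without the replicate 1 libraries), including Ccng1 (0.62), Fas (1.63) and Mdm2 (1.13). Of 29 measured members of the dormancy-associated genes list, 8 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.859). Over all genes, 7 rose and 7 fell. Bhlhe40 (1.92), Gadd45b (1.96) and Bhlhe41 (1.75) rose and the receptor kinase Mertk (-3.64) fell. Nr2f1, a nuclear receptor tied to dormancy, stood at -0.07 ± 0.28 (adjusted p = 0.88), and Sox9 at -0.48 ± 0.22 (0.144). Nr2f1 shares exons with an antisense transcript. In the cholesterol biosynthesis list, 0 of 24 measured members rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000305, and adjusted p = 0.52 with an estimated correlation). A total of 3 fell and 0 rose over all genes. The sterol cyclase Lss (-1.93) was among them. The library means of this list were -1.70 in TGFB2 replicate 1 and -0.52 and -0.72 in replicates 2 and 3, against -0.92, 0.53 and 0.39 in NT replicates 1 to 3, and 20 members fell without the replicate 1 libraries. Of the 13 mitochondrially encoded mRNAs 3 rose, mt-Nd2 by 1.05 (camera adjusted p = 0.00113, and adjusted p = 0.517 with an estimated correlation), and 9 rose without the replicate 1 libraries.

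In all, 1728 genes rose and 1699 fell with TGFB2 among 15319 tested (edgeR), 1851 of them by at least 1 log2 unit. The count was 2018 without NT replicate 2 and 4059 without the replicate 1 libraries. Vim stood at 2.32 ± 0.98 (adjusted p = 0.115) and Bmp4 at 0.08 ± 0.40 (0.91).

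**Figure D2:**
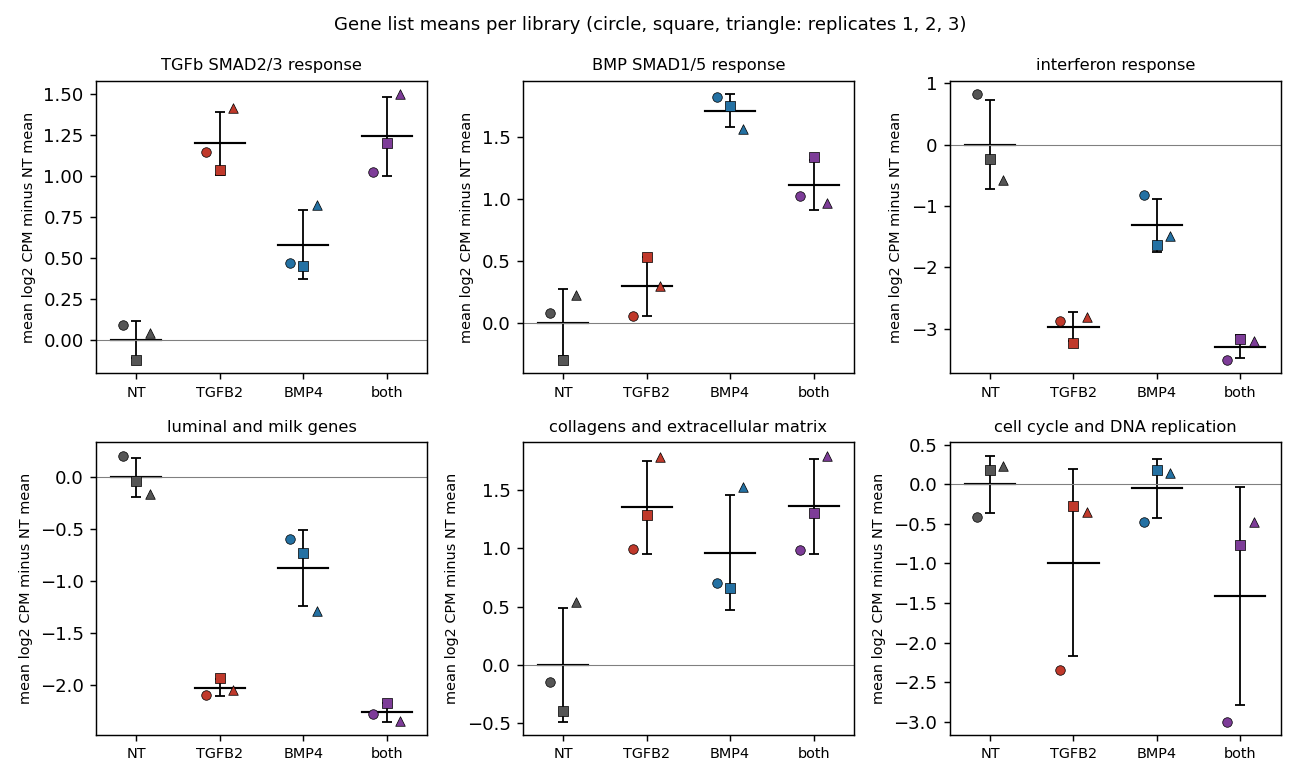
Mean log2 CPM of 6 gene lists in each library minus the NT mean (points), with group means (lines) and SD (bars), n = 3. The interferon list is lower in each treated library than in each NT library, and the cell cycle list is lowest in replicate 1 of TGFB2 and of BMP4-TGFB2.

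BMP4 alone raised collagen VI and BMP targets. Col6a1 and Col6a2, which encode chains of collagen VI, went from 7.88 ± 2.25 CPM to 251 ± 111 CPM and from 2.18 ± 1.2 CPM to 82.8 ± 33.8 CPM, log2 fold changes of 4.99 ± 0.58 (adjusted p = 0.00104) and 5.25 ± 0.71 (0.00234). The matrix-associated gene Ccn5 (4.03), the syndecan Sdc3 (3.95) and the transporter Slc16a12 (3.33) rose as well. Csn3 (ENSMUSG00000001622.15, chromosome 5, 87925579 to 87932665) dropped from 163 ± 50.8 CPM to 2.13 ± 0.556 CPM (-6.26 ± 0.56; adjusted p = 0.000294), and Csn1s1 (-4.73), Fam107a (-2.99), St8sia6 (-2.87) and Nrg1 (-2.72) fell, Nrg1 being a ligand of ERBB receptors. Among the other named changes, Creb3l1 no longer passed with every replicate 1 library left out (adjusted p = 0.0624), at a log2 fold change of -2.93. Chst11 (3.56), Ccl28 (-3.19) and Pigr (-4.07) each lost the call without 2 to 4 of the libraries in turn (adjusted p 0.0509 to 0.0902).

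Of 21 measured members of the BMP SMAD1/5 response list, 17 rose and 0 fell adjusted over the list alone (camera adjusted p = 1.28e-14, and adjusted p = 0.0614 with an estimated correlation). Over all genes, 13 rose and 0 fell (7 and 0 without the replicate 1 libraries). Smad6, an inhibitory SMAD, rose by 2.81 ± 0.25, and the inhibitors of differentiation Id1 (ENSMUSG00000042745.9, chromosome 2, 152736251 to 152737410) and Id3 by 1.12 ± 0.16 and 1.72 ± 0.26. The TGFb SMAD2/3 response list, with 26 members measured, had 11 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 3.23e-07, and adjusted p = 0.194 with an estimated correlation). Over all genes 9 rose and 1 fell, led by Smad7 (1.57), Pmepa1 (1.46), Skil (1.01) and Ltbp2 (1.63). In the TGFb and BMP ligands, receptors and SMADs list, 6 of 32 measured members rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0262, and adjusted p = 0.423 with an estimated correlation). A total of 5 rose and 1 fell over all genes (3 and 0 without the replicate 1 libraries), with Bmp1 (0.86) and Tgfbr1 (0.99) up. With the replicate block the camera adjusted p of this list was 0.0683. Bmp4 rose by 1.97, though it no longer passed without NT replicate 2 or 3 or BMP4 replicate 1 or 2 or with only these groups fitted (adjusted p 0.0516 to 0.073). Of 35 measured members of the collagens and extracellular matrix list, 6 rose and 0 fell adjusted over the list alone (camera adjusted p = 2.35e-05, and adjusted p = 0.381 with an estimated correlation). Over all genes, 4 rose and 0 fell. The luminal and milk genes list, with 20 members measured, had 3 that rose and 9 that fell adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.235 with an estimated correlation). Over all genes 1 rose and 5 fell (1 and 3 without the replicate 1 libraries). Ltf fell (-2.45) and the growth factor Areg rose (1.26). In the basal and myoepithelial genes list, 7 of 17 measured members rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.234 with an estimated correlation). A total of 2 rose and 0 fell over all genes, the keratin Krt15 by 4.60 ± 0.49. The retinoic acid signalling list, with 16 members measured, had 8 that rose and 3 that fell adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.194 with an estimated correlation). Over all genes 4 rose and 3 fell (2 and 1 without the replicate 1 libraries). Rarres1 rose from 0.0576 ± 0.032 CPM to 1.93 ± 0.688 CPM, and the list had a camera adjusted p of 0.0688 without the replicate 1 libraries. In the Wnt targets and feedback list, 7 of 18 measured members rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00204, and adjusted p = 0.194 with an estimated correlation). A total of 4 rose and 0 fell over all genes (2 and 0 without the replicate 1 libraries), with Wnt11 (5.65) and Wnt7b (0.62) as examples.

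Of 34 measured members of the interferon response list, 0 rose and 27 fell adjusted over the list alone (camera adjusted p = 1.49e-15, and adjusted p = 0.26 with an estimated correlation). Over all genes, 11 fell and 0 rose, among them Parp14 (-1.34) and Ifi27l2a (-3.66). The MHC class I antigen presentation list, with 16 members measured, had 0 that rose and 2 that fell adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.423 with an estimated correlation). A total of 0 fell and 0 rose over all genes (3 and 0 without the replicate 1 libraries). With the block Nlrc5, their transcriptional activator (-1.77), had an adjusted p of 0.0273 against 0.050 without it, and H2-K1 (-0.56) 0.0159 against 0.0814. In the cell cycle and DNA replication list, 0 of 42 measured members rose and 0 fell adjusted over the list alone (camera adjusted p = 0.804). A total of 0 fell and 0 rose over all genes, and Mki67 stood at -0.43 ± 0.83 (adjusted p = 0.861). Cdkn1a was at 0.80 ± 0.31 (adjusted p = 0.181, and 0.00139 with the block), and Cdkn1b at -0.06 ± 0.20 (0.929). Nr2f1 fell by 1.36 on the log2 scale (adjusted p = 0.0205), but it no longer passed without NT replicate 1 or 2 or BMP4 replicate 1 or 2, in limma on TPM or with every replicate 1 library left out (adjusted p 0.0537 to 0.482). Of 29 measured members of the dormancy-associated genes list, 6 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.697). Over all genes, 4 rose and 3 fell (3 and 1 without the replicate 1 libraries), with Gadd45b (1.70) up. The mesenchymal and EMT genes list, with 24 members measured, had 4 that rose and 0 that fell adjusted over the list alone (camera adjusted p = 0.00204, and adjusted p = 0.476 with an estimated correlation). Over all genes 3 rose and 0 fell. Of these Fn1 no longer passed without NT replicate 2 or BMP4 replicate 3 or with no filter on low counts (adjusted p 0.0636 to 0.0841), at 2.27, and Snai1 no longer passed without NT replicate 2 (adjusted p = 0.0517), at 1.23. Itgb3 no longer passed without NT replicate 1, 2 or 3 or BMP4 replicate 3, with no filter on low counts, in limma voom, in limma on TPM, with only these groups fitted or with every replicate 1 library left out (adjusted p 0.0547 to 0.299), at 2.69. Values for Sox9, Cdh1, Vim and Tgfb2 were -0.16 ± 0.22, -0.07 ± 0.10, -0.24 ± 0.94 and -0.30 ± 0.32, with adjusted p of 0.783, 0.769, 0.941 and 0.694.

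BMP4 raised 489 genes and lowered 341 (edgeR), 499 by at least 1 log2 unit. With the replicate number as a block the count was 2364, in DESeq2 1569, and without the replicate 1 libraries 661. It was 296 without NT replicate 2, 502 without BMP4 replicate 1, 494 without BMP4 replicate 2 and 456 without BMP4 replicate 3. The block brought the cholesterol list (camera adjusted p = 0.00134, lower) and the fibroblast markers (0.0191, higher) past the threshold. Without the block camera called 16 lists, 12 higher and 4 lower, not all described here. The p53 targets list had library means of 0.59, 0.26 and 0.30 with BMP4, against 0.37, -0.27 and -0.10 in NT. Without the replicate 1 libraries 5 of its 24 members rose and 0 fell (camera adjusted p = 1.76e-06 at the preset correlation).

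With both ligands Itgb3 rose and Ltf fell. Itgb3 reached 41.7 ± 20 CPM (6.16 ± 0.63 against NT; adjusted p = 6.69e-05), and Ltf stood at 98.6 ± 27.2 CPM (-6.70 ± 0.39; 2.67e-06). Further rises were Adgra1 (7.39), Ptpru (6.41), Chst11 (6.25) and Olfm2 (5.74), and further falls Csn1s1 (-7.30), Csn3 (-7.17), Pigr (-7.02), Pip (-6.89), St8sia6 (-6.55) and Rasal1 (-6.14). Mmp9 rose by 7.50, but it no longer passed in limma voom (adjusted p = 0.0612). Of 26 measured members of the TGFb SMAD2/3 response list, 18 rose and 2 fell adjusted over the list alone (camera adjusted p = 3.22e-08, and adjusted p = 0.245 with an estimated correlation). Over all genes, 17 rose and 0 fell, and Smad7, an inhibitor of both branches, rose by 2.16 ± 0.14. The BMP SMAD1/5 response list, with 21 members measured, had 9 that rose and 0 that fell adjusted over the list alone (camera adjusted p = 0.000932, and adjusted p = 0.392 with an estimated correlation). Over all genes 8 rose and 0 fell, with Smad6 (2.45) and Id1 (0.91). Nog, a secreted BMP antagonist, rose from 0.0189 ± 0.0327 CPM to 1.58 ± 0.244 CPM, and with NT near 0 its log2 fold change is not well fixed. In the TGFb and BMP ligands, receptors and SMADs list, 13 of 32 measured members rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.483 with an estimated correlation). A total of 12 rose and 3 fell over all genes. Bmp1 (2.31), Bmp2 (3.33) and Inhba (3.20) rose. Of 24 measured members of the mesenchymal and EMT genes list, 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.83e-05, and adjusted p = 0.458 with an estimated correlation). Over all genes, 13 rose and 1 fell, and Fn1 rose by 3.22 ± 0.49. The collagens and extracellular matrix list, with 35 members measured, had 19 that rose and 0 that fell adjusted over the list alone (camera adjusted p = 7.35e-06, and adjusted p = 0.458 with an estimated correlation). Over all genes 16 rose and 0 fell, such as P4ha1 (1.62) and Col7a1 (4.85). Of the fibroblast markers, 4 of 13 rose as well (camera adjusted p = 0.0195, and adjusted p = 0.535 with an estimated correlation).

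In the luminal and milk genes list, 2 of 20 measured members rose and 12 fell adjusted over the list alone (camera adjusted p = 1.39e-06, and adjusted p = 0.245 with an estimated correlation). A total of 2 rose and 11 fell over all genes. Of 34 measured members of the interferon response list, 0 rose and 32 fell adjusted over the list alone (camera adjusted p = 1.68e-22, and adjusted p = 0.353 with an estimated correlation). Over all genes, 32 fell and 0 rose, with Oas3 (-4.40), Cmpk2 (-4.43) and Rtp4 (-3.49). With the replicate 1 libraries left out 30 members fell and 1 rose. The MHC class I antigen presentation list, with 16 members measured, had 0 that rose and 14 that fell adjusted over the list alone (camera adjusted p = 1.39e-06, and adjusted p = 0.392 with an estimated correlation). A total of 12 fell and 0 rose over all genes. In the NF-kB, cytokines and acute-phase genes list, 6 of 34 measured members rose and 15 fell adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.458 with an estimated correlation). A total of 4 rose and 13 fell over all genes, with Cxcl3 (-4.53) and Ccl20 (-4.84). Without the replicate 1 libraries its camera adjusted p was 0.132. Of 42 measured members of the cell cycle and DNA replication list, 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 6.55e-06, and adjusted p = 0.621 with an estimated correlation). Over all genes, 4 fell and 0 rose. The members that fell were Ccne1 (-1.48), E2f8 (-2.10), Mcm7 (-0.78) and Tyms (-1.04), and each lost its call without 4 to 5 of the libraries in turn (adjusted p 0.0505 to 0.146). Mcm7 shares exons with Cops6 and Ap4m1, at 70.5% and 12.9% of its mean CPM. The list mean was -3.00 in replicate 1 of this group and -0.77 and -0.47 in replicates 2 and 3. Without the replicate 1 libraries 38 members fell (camera adjusted p = 7.68e-15 at the preset correlation only). Cdkn1a rose (1.48), and Cdh1 (-0.50 ± 0.10; adjusted p = 0.00342) and Tgfb2 (-1.65) fell. Values that did not pass were Nr2f1 -0.79 ± 0.29 (adjusted p = 0.0635), Cdkn1b -0.31 (0.294), Sox9 -0.47 (0.136), Mki67 -1.68 ± 0.85 (0.174), Vim 1.80 ± 0.96 (0.196) and Bmp4 -0.38 (0.535). In the dormancy-associated genes list, 9 of 29 measured members rose and 10 fell adjusted over the list alone (camera adjusted p = 0.963). A total of 7 rose and 9 fell over all genes, with Bhlhe40 (2.11), Gadd45b (2.36) and Tyro3 (1.10) up and Mertk (-4.27) down. Of the mitochondrially encoded mRNAs 3 rose (camera adjusted p = 0.0033, and adjusted p = 0.535 with an estimated correlation), and 7 did without the replicate 1 libraries. In all 2037 genes rose and 1971 fell (edgeR), 2201 by at least 1 log2 unit. The count was 2523 without NT replicate 2 and 4696 without the replicate 1 libraries.

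**Figure D3:**
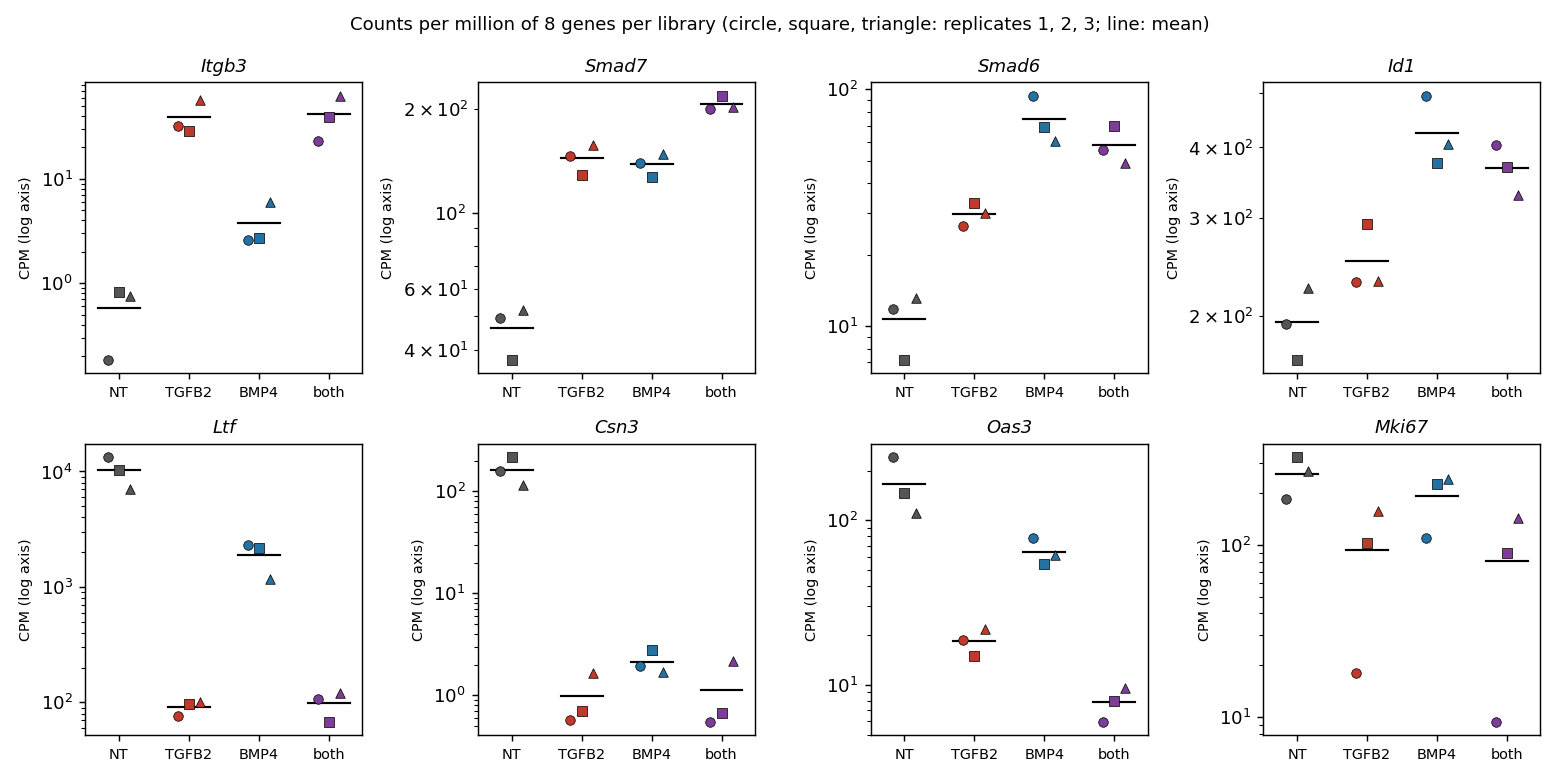
CPM of 8 genes in each library on log axes (points) with group means (lines), n = 3. Ltf falls from 10250 CPM in NT to 90.8 with TGFB2, 1878 with BMP4 and 98.6 with both, and Mki67 is lowest in replicate 1 of the groups with TGFB2.

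The comparison of BMP4-TGFB2 with TGFB2 asks what BMP4 adds to TGFB2, and no gene passed in edgeR: 508 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.209. BMP targets stood higher as a set. Of 21 measured members of the BMP SMAD1/5 response list, 9 rose and 0 fell adjusted over the list alone (camera adjusted p = 5.4e-16, and adjusted p = 0.0439 with an estimated correlation). Over all genes, 0 fell and 0 rose, the median member standing at 0.84. Id2 stood at 1.06 ± 0.16 (adjusted p = 0.209), Atoh8 at 1.57 ± 0.36 (0.588), Smad6 at 0.96 ± 0.23 (0.723), Id3 at 0.94 ± 0.26 (0.917) and Id1 at 0.55 ± 0.16 (0.961). Lists that stood lower by camera were interferon (median -0.37; camera adjusted p = 1.56e-05), cell cycle (-0.32; 0.00107), cytokines (-0.21; 0.0301), luminal genes (-0.16; 0.0482, and 0.12 without the replicate 1 libraries) and adipocyte and erythroid markers (-0.63; 0.0102). Each of these 5 had an adjusted p = 0.999 with an estimated correlation, and no member passed over all genes. With the replicate block 10 genes passed, Id2 among them (adjusted p = 0.00649), and 3 lists stood higher that had not passed: epithelial junction genes (camera adjusted p = 0.0292), actin and YAP targets (0.0112) and cholesterol biosynthesis (0.000807). DESeq2 called 51 genes, limma voom 0, limma on TPM 1, edgeR with no filter 9, with only these groups 2 and without BMP4-TGFB2 replicate 1 1. A p above the threshold does not show that the groups were alike.

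The comparison of BMP4-TGFB2 with BMP4 asks what TGFB2 adds to BMP4. Against BMP4, BMP4-TGFB2 cells had more Adgra1 (4.90 ± 0.66; adjusted p = 0.00146) and Olfm2 (3.87), and less Ltf (-4.25 ± 0.35; 0.000167), Klk14 (-5.39), Klk10 (-4.43) and Elf5 (-3.24). The keratin Krt15 went from 17.4 ± 7.95 CPM to 0.143 ± 0.0799 CPM (-6.93 ± 0.57), and Bmp4 fell (-2.35). Stab1 (3.59) shares exons with Nt5dc2. Mmp9 no longer passed without BMP4 replicate 1 or 2 or BMP4-TGFB2 replicate 1, 2 or 3, with no filter on low counts, in limma voom, with only these groups fitted or with every replicate 1 library left out (adjusted p 0.0505 to 0.182), and its log2 fold change was 5.49. The TGFb SMAD2/3 response list, with 26 members measured, had 11 that rose and 0 that fell adjusted over the list alone (camera adjusted p = 2.37e-06, and adjusted p = 0.297 with an estimated correlation). Over all genes 9 rose and 0 fell, with Bhlhe40 (1.60), Smurf1 (0.82) and Pmepa1 (0.77). In the BMP SMAD1/5 response list, 2 of 21 measured members rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.579 with an estimated correlation). A total of 5 fell and 0 rose over all genes (1 and 0 without the replicate 1 libraries), Atoh8 by -1.96. Of 20 measured members of the luminal and milk genes list, 1 rose and 10 fell adjusted over the list alone (camera adjusted p = 1.18e-06, and adjusted p = 0.297 with an estimated correlation). Over all genes, 10 fell and 0 rose (6 and 0 without the replicate 1 libraries). The interferon response list, with 34 members measured, had 0 that rose and 31 that fell adjusted over the list alone (camera adjusted p = 1.1e-21, and adjusted p = 0.297 with an estimated correlation). A total of 23 fell and 0 rose over all genes, such as Oas3 (-3.04) and Cmpk2 (-2.79). In the NF-kB, cytokines and acute-phase genes list, 0 of 34 measured members rose and 12 fell adjusted over the list alone (camera adjusted p = 0.000281, and adjusted p = 0.297 with an estimated correlation). A total of 8 fell and 0 rose over all genes (5 and 0 without the replicate 1 libraries), with Cxcl3 (-3.80) and Ccl20 (-3.34). Of 42 measured members of the cell cycle and DNA replication list, 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 1.64e-08, and adjusted p = 0.684 with an estimated correlation). Over all genes, 0 fell and 0 rose. Without the replicate 1 libraries, a fit chosen after seeing the data, 34 members fell and 0 rose, with a median of -0.79. That fit has 2 libraries per group. It drops the BMP4-TGFB2 library with the lowest list mean, -3.00 against -0.77 and -0.47 in replicates 2 and 3. Its camera adjusted p was 3.56e-25, at the preset correlation only. Pcna stood at -0.59 ± 0.20 (adjusted p = 0.10, and 0.0038 with the block) and Ccne1 at -1.28 ± 0.45 (0.11, and 0.000444). With the block Cdkn1a (0.68; adjusted p = 0.00216 against 0.212) and Vim (2.04; 0.0138 against 0.237) passed too, as did the lists of p53 targets (camera adjusted p = 0.0403, higher), Wnt targets (0.0267, lower) and fibroblast markers (0.0479, higher). Of the mitochondrially encoded mRNAs 1 was higher, mt-Nd2 at 0.83, and the median was 0.44 (camera adjusted p = 0.00582, and adjusted p = 0.684 with an estimated correlation). mt-Nd2 no longer passed without BMP4 replicate 1, 2 or 3 or BMP4-TGFB2 replicate 1 or 2, in limma on TPM, with only these groups fitted or with every replicate 1 library left out (adjusted p 0.0509 to 0.167). In all 641 genes were higher and 753 lower (edgeR), 834 by at least 1 log2 unit. The count was 3446 with the block, 2219 in DESeq2 and 1382 without the replicate 1 libraries. It was 848 without BMP4 replicate 1, 653 without BMP4 replicate 2, 827 without BMP4-TGFB2 replicate 1 and 837 without BMP4-TGFB2 replicate 3.

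The single ligands compared directly showed the BMP list higher with BMP4. Of 21 measured members of the BMP SMAD1/5 response list, 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.19e-08, and adjusted p = 0.295 with an estimated correlation). Over all genes, 12 rose and 0 fell (7 and 0 without the replicate 1 libraries), with Id2 (1.63), Atoh8 (3.53), Hey1 (4.05) and Id3 (1.60). The TGFb SMAD2/3 response list, with 26 members measured, had 1 that rose and 9 that fell adjusted over the list alone (camera adjusted p = 7.16e-05, and adjusted p = 0.35 with an estimated correlation). A total of 8 fell and 0 rose over all genes, such as Bhlhe40 (-1.40), Ski (-0.74) and Pmepa1 (-0.78). Col6a1 (4.49 ± 0.56; adjusted p = 0.00105), Col6a2 (4.43), Klk14 (5.40) and Krt15 (7.29 ± 0.58; 0.000185) were higher with BMP4, and Adgra1 (-5.07), the membrane glycoprotein Gpm6b (-3.60), Itgb3 (-3.38) and Creb3l1 (-3.37) lower. In the luminal and milk genes list, 9 of 20 measured members rose and 1 fell adjusted over the list alone (camera adjusted p = 3.07e-05, and adjusted p = 0.325 with an estimated correlation). A total of 8 rose and 0 fell over all genes (4 and 0 without the replicate 1 libraries), with Ltf (4.37), Elf5 (2.42) and Kit (4.29). Of 34 measured members of the interferon response list, 31 rose and 0 fell adjusted over the list alone (camera adjusted p = 1.29e-18, and adjusted p = 0.35 with an estimated correlation). Over all genes, 17 rose and 0 fell. The epithelial junction and identity genes list, with 30 members measured, had 6 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.000731, and adjusted p = 0.495 with an estimated correlation). Over all genes 6 rose and 0 fell (3 and 1 without the replicate 1 libraries), with Cldn1 (3.28) and Grhl1 (3.54). In the collagens and extracellular matrix list, 2 of 35 measured members rose and 10 fell adjusted over the list alone (camera adjusted p = 0.0033, and adjusted p = 0.587 with an estimated correlation). A total of 2 rose and 9 fell over all genes (2 and 4 without the replicate 1 libraries), Col18a1 by -1.27. Nr2f1 no longer passed without TGFB2 replicate 1 or 3 or BMP4 replicate 1 or 2, in limma on TPM or with every replicate 1 library left out (adjusted p 0.0503 to 0.504), being lower with BMP4 at -1.29. The mitochondrially encoded mRNAs were lower with BMP4, with a median of -0.51 (camera adjusted p = 0.00147, and adjusted p = 0.548 with an estimated correlation). Of them 1 passed, mt-Nd2 at -0.92, and without the replicate 1 libraries 2 did. mt-Nd2 no longer passed without TGFB2 replicate 1 or 2 or BMP4 replicate 1, 2 or 3 (adjusted p 0.0718 to 0.119). Fibroblast markers had a median of -0.57 (camera adjusted p = 0.0436, and 0.0648 without the replicate 1 libraries) and adipocyte and erythroid markers -0.93 (0.0489, and 0.135), with an estimated correlation at adjusted p = 0.614 and adjusted p = 0.548. In all 630 genes were higher and 559 lower with BMP4 than with TGFB2 (edgeR), 753 by at least 1 log2 unit. The count was 2990 with the block, 1977 in DESeq2 and 883 without the replicate 1 libraries. It was 652 without TGFB2 replicate 1, 621 without TGFB2 replicate 3, 704 without BMP4 replicate 1 and 548 without BMP4 replicate 2. With the block Cdkn1a (adjusted p = 0.00368) and Vim (0.00265) passed, lower with BMP4, and so did Cdkn1b (0.0394), higher with BMP4. The actin and YAP list passed too (camera adjusted p = 0.0183, lower) and the list of ligands and receptors did not (0.103).

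Genes called against NT for both single ligands, such as Smad7, Skil, Pmepa1, Csn3 and Ltf, moved the same way in most cases. Of them 340 rose with each ligand and 296 fell with each, against 55.2 and 37.8 for independent lists, and 15 moved in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.63. In a simulation with all 12 libraries, NT included, drawn anew from the NT means, 20 draws gave 0.50. Unlike the data, these draws held no effect of a ligand or of the replicate number. The covariance was 0.64 against a simulated 0.16, a difference of 0.48. Simulated calls in both numbered 0, but no drawn gene had an effect. That 0 was nearly fixed in advance and gives no baseline for the 340 and 296. The 3 NT libraries cannot be split into 2 groups of 2, so part of the excess may come from the shared controls. With the block 1878 genes were shared in the same direction, and in DESeq2 1185.

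The interaction asks whether the response to both ligands differs from the sum of the single responses on the log2 scale. Csn3 had the largest positive term, 6.47 ± 0.76 (adjusted p = 0.0255). Its log2 fold changes against NT were -7.38 with TGFB2, -6.26 with BMP4 and -7.17 with both. It stood at 0.979 ± 0.597 CPM, 2.13 ± 0.556 CPM and 1.14 ± 0.915 CPM in these groups. From such levels a fall as large as the sum of the single ones could hardly be counted. The Csn3 term thus does not show that the ligands interact. Igsf11, an adhesion molecule, had a term of -2.83 ± 0.30 (adjusted p = 0.0136), with 3.38 ± 1.01 CPM in NT, 39 ± 5.93 CPM with TGFB2, 21.6 ± 2.46 CPM with BMP4 and 35 ± 5.29 CPM with both. Csn3 no longer passed without TGFB2 replicate 2 or BMP4 replicate 1 or 2 or with every replicate 1 library left out (adjusted p 0.0523 to 0.148), and Igsf11 no longer passed without TGFB2 replicate 2 (adjusted p = 0.0594). Terms that did not pass were Smad7 -1.05 ± 0.19 (adjusted p = 0.0641), Id1 -0.57 ± 0.22 (0.478), Fn1 -2.45 ± 0.64 (0.207) and Bmp4 -2.43 ± 0.58 (0.17). In all 7 genes had a positive and 16 a negative term (edgeR). The count was 298 in DESeq2, 79 with no filter, 14 in limma voom and 5 without the replicate 1 libraries. It was 4 without NT replicate 2, 11 without TGFB2 replicate 1, 0 without TGFB2 replicate 2, 7 without TGFB2 replicate 3, 1 without BMP4 replicate 1, 2 without BMP4 replicate 2, 12 without BMP4 replicate 3, 2 without BMP4-TGFB2 replicate 1, 2 without BMP4-TGFB2 replicate 2 and 4 without BMP4-TGFB2 replicate 3.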

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

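The tests of the counting floor were chosen after the result was seen, and the pattern they weigh was itself found in the data. The results below stood out because the effect of one ligand differed with the other present, by the interaction test in edgeR. 23 genes and 15 lists (camera) did so. The 5 largest positive terms were Csn3 (6.47), Csn1s1 (4.89), the cytoskeletal gene Gas7 (2.78), Ogfrl1 (1.84) and Gne (1.45), an enzyme of sialic acid synthesis. Csn3 was close to the counting floor with each ligand alone, so its term can come from the floor. The same may hold for Csn1s1, which also fell with each ligand. The 5 largest negative terms were Ccn5 (-4.70), Sdc3 (-3.04), Igsf11 (-2.83), the protease Prss23 (-2.45) and Ttyh2 (-2.31), and from the lists Pmepa1 (-1.47) and Bmp1 (-0.95) passed too. None of these 12 kept its call in each fit with 1 library left out. Igsf11 lost it without TGFB2 replicate 2 alone (adjusted p = 0.0594), and the others without 3 to 12 of the 12 libraries, TGFB2 replicate 2 among them in each case.

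Lists with a negative median term were TGFb SMAD2/3 response (-0.50), BMP SMAD1/5 response (-0.78), ligands and receptors (-0.14), mesenchymal genes (-0.48), matrix (-0.80), basal genes (-0.93), actin and YAP (-0.23), p53 targets (-0.34), retinoic acid signalling (-0.59), Wnt targets and feedback (-0.82) and immediate early genes (-0.34). Lists with a positive median were luminal and milk genes (0.47), interferon response (0.89), MHC class I (0.19) and fatty acid synthesis (0.37). Their camera adjusted p ran from 7.87e-09 to 0.0231, and with an estimated correlation the adjusted p of each was 0.225 or more. Without the replicate 1 libraries the retinoic acid list had a camera adjusted p of 0.0502. The medians of luminal, MHC class I and mesenchymal genes were then 0.16, 0.30 and -0.82. Camera also called cell cycle and DNA replication (-0.27), CDK inhibitors and quiescence (-0.28), cholesterol biosynthesis (0.53), oxidative phosphorylation (0.20) and mitochondrially encoded mRNAs (-0.40) there.

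A pattern runs through these terms. The 636 genes called in the same direction by each ligand had a median absolute log2 fold change of 1.62 with TGFB2, 1.27 with BMP4 and 1.92 with both, a median shortfall from the sum of -0.97. If selection of genes on noise shared through NT were the cause, the shortfall would vanish where genes are chosen on 2 replicate numbers and measured on the remaining one. It did not vanish: the held-out medians were -0.72, -1.72 and -1.22 for 573, 15 and 256 genes. Their mean was -1.22 (SE 0.288), each set counted alike whatever its size. The 15 genes had median held-out responses of 3.19 with TGFB2 and 2.49 with BMP4, against 1.21 and 0.88 for the 573. That SE reflects unlike gene sets and does not measure the spread between replicates. Values near the counting floor would lift the NT value of genes that rose and so add to their interaction. The 340 genes that rose had a median of -1.17, and -0.97, -1.25 and -1.06 by replicate number. Of the 296 that fell, 145 had a level predicted by the sum of at least 10 CPM, where the floor is far. Their median was -0.63, and -0.68, -0.63 and -0.54 by number. These genes were chosen on the same libraries that gave their medians, and such a choice favours a shortfall with or without a floor. All replicate numbers took part in it, so the medians by number are not independent checks. The held-out medians were not split into rises and falls. These values thus do not decide what part the floor had. For falls predicted below 10 CPM the floor stays open as well. A sum on the log2 scale stands for folds that multiply, so responses that add in transcript number would fall short of it as well. A limit shared by both pathways, such as common SMAD4, may hold the joint response below that sum. This is a hypothesis that no test here reached.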

How the results depend on the processing

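The alternative without the replicate 1 libraries was chosen after seeing the data. Counts kept within 1.5 times with RLE size factors in all 7 comparisons, and RLE moved the median log2 fold change by less than 0.01 in each. Leaving out single libraries gave 2018 to 3630 genes for TGFB2 against NT, 296 to 752 for BMP4, 2523 to 4200 for BMP4-TGFB2, 0 to 1 for BMP4-TGFB2 against TGFB2, 653 to 1297 against BMP4, 548 to 1120 for BMP4 against TGFB2 and 0 to 28 for the interaction. The replicate block gave 5764 genes for TGFB2 against NT, 2364 for BMP4, 6328 for BMP4-TGFB2, 10 for BMP4-TGFB2 against TGFB2, 3446 against BMP4, 2990 for BMP4 against TGFB2, 311 for the interaction and 1878 for the overlap. In TGFB2 against NT and BMP4-TGFB2 against NT the correlations of same-numbered libraries, 0.08 to 0.30 and 0.03 to 0.23, did not all exceed 0.1. The block was therefore left out there. Yet each of the 12 libraries correlated best with its own number, and the same numbers were treated as pairs in the other comparisons of groups. Genes that did not pass in TGFB2 or BMP4-TGFB2 against NT may thus pass once the numbers are taken as pairs. In the paired comparisons the block changed no list call other than those in the report. In TGFB2 against NT it ended the call of the cytokine list (camera adjusted p = 0.0804) and brought in immediate early genes (0.0259), and in BMP4-TGFB2 against NT it ended that of ligands and receptors (0.10) and brought in immediate early genes (0.0464). For the interaction it ended that of ligands and receptors (0.055) and brought in cell cycle (0.0154), cholesterol (1.55e-06) and fibroblast markers (0.0183). DESeq2 gave 1569 for BMP4, 51, 2219 and 1977 for the comparisons between treatments in the order above, 298 for the interaction and 1185 for the overlap. For BMP4-TGFB2 against TGFB2 no filter gave 9, TPM 1 and a fit of those groups 2. For the interaction no filter gave 79, voom 14 and the fit without replicate 1 5. The fits of fewer samples have fewer degrees of freedom. The cause of the other differences was not tested. Of the lists called by camera, 0, 0, 0, 1, 0, 0 and 0 passed with an estimated correlation in the 7 comparisons, and fry called 15 lists for TGFB2, 9 for BMP4, 18 for BMP4-TGFB2, 0 for BMP4-TGFB2 against TGFB2, 8 against BMP4, 10 for BMP4 against TGFB2 and 0 for the interaction.

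Of 559 gene results, 335 kept direction and side of the threshold under each alternative. Sign changes concerned genes that had not passed: Bmp4 in BMP4-TGFB2 against NT was 0.19 on TPM and 0.14 without replicate 1, and in BMP4-TGFB2 against TGFB2 on TPM Sox9 was -0.0017 and Tgfb2 -0.23. With single libraries left out, log2 fold changes ran across 0 for Bmp4 -0.24 to 0.61 and Nr2f1 -0.24 to 0.0418 (TGFB2 against NT), Cdkn1b -0.29 to 0.18, Sox9 -0.40 to 0.10 and Vim -0.89 to 0.17 (BMP4), Bmp4 -0.70 to 0.15 (BMP4-TGFB2), Cdkn1a -0.14 to 0.26, Fn1 -0.49 to 0.13, Mki67 -0.91 to 0.41, Sox9 -0.11 to 0.12, Tgfb2 -0.0637 to 0.42 and Vim -2.11 to 0.53 (against TGFB2), Smad7 -0.14 to 0.00821 (BMP4 against TGFB2) and Cdkn1b -0.0406 to 0.43, Mki67 -0.48 to 0.84, Sox9 -0.10 to 0.39 and Vim -1.87 to 0.77 (interaction). The cause was not tested. Depth limits genes near the minimum count of 10, and in simulations of the interaction 4.48% of genes changed by 1 log2 unit passed.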

Other observations

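The tests of a scaling error and of an additive replicate 1 effect on the cell cycle list, and those for the interferon list other than that of NT replicate 1 in TGFB2 against NT, were chosen after the result was seen. Further lists were tested for TGFB2. Of 25 measured members of the fatty acid synthesis and lipid storage list, 1 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.0136, and adjusted p = 0.42 with an estimated correlation). Over all genes, 1 rose and 10 fell. Elovl6 (-2.76), which lengthens fatty acids, and the binding protein Fabp5 (-2.39) fell, and the droplet protein Plin2 rose (1.42). The glycolysis and hypoxia list, with 25 members measured, had 5 that rose and 6 that fell adjusted over the list alone (camera adjusted p = 0.625). Over all genes 5 rose and 5 fell (6 and 9 without the replicate 1 libraries), with the lactate exporter Slc16a3 (2.64) up and Pdk1 (-1.22) and Egln3 (-3.06) down. In the oxidative phosphorylation, nuclear encoded list, 0 of 30 measured members rose and 10 fell adjusted over the list alone (camera adjusted p = 0.00926, and adjusted p = 0.52 with an estimated correlation). A total of 6 fell and 0 rose over all genes, Atp5c1 by -0.49. Of 28 measured members of the unfolded protein response and integrated stress list, 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.374). Over all genes, 1 rose and 6 fell (8 and 8 without the replicate 1 libraries). Ddit4, an inhibitor of mTOR signalling, rose (2.10) and Xbp1 (-0.96) and Psat1 (-1.54) fell. The retinoic acid signalling list, with 16 members measured, had 1 that rose and 3 that fell adjusted over the list alone (camera adjusted p = 0.68). Over all genes 1 rose and 3 fell, and Aldh1a3, which makes retinoic acid, rose by 3.73. In the Wnt targets and feedback list, 4 of 18 measured members rose and 2 fell adjusted over the list alone (camera adjusted p = 0.851). A total of 3 rose and 2 fell over all genes: Wnt7b (1.11) and Wnt7a (4.20) rose and the Wnt antagonist Wif1 (-4.44) fell. Of 17 measured members of the Notch pathway list, 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.329). Over all genes, 6 rose and 2 fell. The ligand Jag1 rose by 4.58 ± 0.46, and Dtx1 (-4.45) and Rfng (-1.41) fell. The immediate early and dissociation genes list, with 24 members measured, had 8 that rose and 4 that fell adjusted over the list alone (camera adjusted p = 0.0572). Over all genes 8 rose and 3 fell (10 and 5 without the replicate 1 libraries), Junb (1.92) and Egr2 (2.35) among them.

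Marker lists gave values for other cell types and for RNA quality. With TGFB2, 0 of 10 endothelial markers passed (camera adjusted p = 0.629), and 1 of 7 adipocyte and erythroid markers rose (0.127), the globin Hba-a2, at 2.29. Hba-a2 no longer passed without NT replicate 2 or TGFB2 replicate 3 or with every replicate 1 library left out (adjusted p 0.0534 to 0.062). Of 43 ribosomal protein genes 0 rose and 0 fell with TGFB2 (0.941). CT010467.1, a gene outside the rule that was picked after its values were seen, was the most abundant in TGFB2 replicate 2 (1.09% of counts) and in BMP4 replicate 3 (2.25%).

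The cell cycle list fell furthest in replicate 1 of the groups with TGFB2: its median difference between replicate 1 and replicates 2 and 3 was -2.32 with TGFB2 and -2.67 with both, against -0.68 in NT and -0.70 with BMP4. A scaling error of those libraries would move all genes alike, but the list lay -2.32 from the median of all tested genes in TGFB2. A replicate 1 effect that adds alike in every group was argued against by fry, which gave an adjusted p = 0.00395 over 31 lists for a further lowering in the groups with TGFB2. The unadjusted fry value was 0.000127. The same fry term was negative for CDK inhibitors (adjusted p = 0.0118), MHC class I (0.0118), dormancy (0.0174) and Notch (0.040) as well. Unlike the cell cycle list, these lists were highest in replicate 1 of NT and of BMP4. With TGFB2 the CDK inhibitor mean was 0.15 in replicate 1 and 0.20 and 0.042 in replicates 2 and 3. Their terms thus do not show whether the fall is special to the cell cycle. That the cultures of replicate 1 responded otherwise to TGFB2, less cycling included, is a hypothesis, consistent with these values and found on the same data. What set them apart is not in the labels and was not tested.

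The interferon list fell in each comparison with NT. Fewer leukocytes in the treated cultures would lower leukocyte markers, whose median against NT was 0.85 with TGFB2, 0.46 with BMP4 and 0.51 with both. The most abundant of the 7 measured, Cd68, had 2.35 CPM in NT and 4.24 with TGFB2. The least abundant in NT, Laptm5, had 0.085 CPM there and 0.427 with TGFB2. At levels so near the floor these medians cannot decide whether leukocytes were lost. Scaling would move all genes, and the list lay -3.07, -1.38 and -3.56 from their median in the same order. NT replicate 1, in which the list was highest, did not carry the result with TGFB2 or with both, since 100% and 96.9% of the called members passed without it. With BMP4 63.6% did, 7 of 11. With every replicate 1 library left out, 11 members fell and 0 rose with BMP4, at a median of -1.16. The list means were -0.82, -1.63 and -1.49 with BMP4, and -0.24 and -0.58 in NT replicates 2 and 3. These values argue against NT replicate 1 as the sole source of the fall with BMP4. Its part in the size of that fall stays open. A lower interferon tone under the ligands may account for the fall, as a hypothesis. Neither interferon nor its receptors' activity was measured.

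Other splits of the libraries give the counts when the treatments are mixed within each side. For each comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. Each side of another split holds libraries of both treatments, so treatment effects enter the spread and can hold the count down. These counts are therefore not taken to exclude chance. The real count and the highest of the other splits were 3427 and 1 for TGFB2 against NT, 830 and 0 for BMP4, 4008 and 0 for BMP4-TGFB2, 0 and 0 for BMP4-TGFB2 against TGFB2, 1394 and 0 against BMP4, and 1189 and 1 for BMP4 against TGFB2. A result as large came from 1 split in each of these but BMP4-TGFB2 against TGFB2, where all 10 gave 0. In the paired comparisons the other splits that part all 3 pairs gave at most 1, in BMP4 against TGFB2, and those that part fewer gave 0. For the interaction 4 of 100 random assignments, the real one included, gave 23 or more, a share under 0.05. These assignments mix the treatments and ignore the replicate numbers, so treatment effects enter their spread, and the share alone is not taken to exclude chance. The highest other gave 3698. An assignment that lines up with the treatments would carry their effects into the interaction term, but whether this one did was not examined.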
